A study of Homo sapiens with 30 samples.

How the data were processed

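Human HEK-Blue ISG cells with STING (WT) and the HEK-Blue ISG-KO-STING line (knockout) were compared after transfection with a plasmid holding dacA of Listeria monocytogenes, which makes cyclic di-AMP, or its D171N form, which the labels call catalytically inactivated. The labels name the constructs DLM and DLM D171N; DLM is read here as the unmutated dacA, since only the other carries the mutation. RNA was taken 12 h or 24 h after transfection with Lipofectamine, and from untransfected cells with no time given. Each of the 10 groups has 3 libraries, marked a, b and c, 30 in all and 15 per line. The labels name no mock transfection, and reads of the plasmid are not part of the tables.

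Per the labels, the authors isolated RNA with RNeasy columns and sequenced polyA RNA in paired ends on an Illumina NextSeq. HISAT2, SAMtools and featureCounts of the Subread package with genome build GRCh38 are named in the submitters' processing notes, without versions or annotation. The deposited tables, 1 per line, hold raw counts per gene symbol, 60591 symbols in each, as whole numbers with a different total in each column. All columns were used. Library totals were 14.3 to 26.9 M counts in WT (median 20.6 M) and 8.72 to 29.5 M in knockout libraries (median 12.3 M).

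Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15) with the groups as design, library sizes were scaled by trimmed means of M values (TMM), and quasi-likelihood negative binomial models with robust dispersion were fitted with 1 mean per group. Comparisons within a line used the 15 libraries of that line (19368 genes in WT, 16879 in knockout). The difference of the DLM effect between lines at each time (the effect in WT minus that in knockout cells) and the comparison of untransfected lines used a fit of all 30 libraries (19901 genes). There were 17 comparisons: DLM against D171N, D171N against untransfected and DLM against untransfected at each time in each line, the change of the DLM effect from 12 h to 24 h in each line, the difference between lines at each time, and knockout against WT without transfection. p-values come from the edgeR quasi-likelihood F test, adjusted by Benjamini and Hochberg over the genes of a comparison, and genes with an adjusted p under 0.05 are called. Standard errors, given after ± throughout, are the absolute log2 fold change divided by the square root of F. Levels are CPM, computed by the cpm function of edgeR from TMM-scaled library sizes, and group levels are means of 3 libraries.

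Before the data were examined, 21 gene lists were fixed: interferon-stimulated genes, interferons and IRF3-induced chemokines, NF-kB targets, antigen presentation by MHC class I, nucleic acid sensing, the unfolded protein response of the endoplasmic reticulum, ATF4 and amino acid response, p53 targets, heat shock response, immediate early genes, cholesterol biosynthesis, hypoxia response, S phase and replication, G2 and mitosis, NRF2 oxidative stress response, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, replication-dependent histones, leukocyte and monocyte markers, and fibroblast and keratinocyte markers. DDX58, listed as RIGI, was not matched to the tables and is in no list tally or list test. Lists with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals, each adjusted over the lists of a comparison. Counts adjusted over the list alone apply the Benjamini and Hochberg step to the p-values of that list's members only.

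The genes to be named were also fixed by rule. They are STING1, CGAS, TBK1, IRF3, IFNB1 and ALPP; the up to 10 genes per direction with the largest change in the DLM against D171N comparisons and in the differences between lines, and up to 5 in the others; and up to 4 members with the smallest p from each list. The largest changes were taken among called genes with a mean of at least 1 CPM and, for comparisons of 2 groups, with all 3 libraries of one group above all 3 of the other. Of the genes the rule picks, those whose fold moved by over 1.5 times without 1 library or with DESeq2 or the replicate block were mostly left out after the values were seen, and the others are given with the other value. Clone-based and antisense names were left out, and pseudogenes and the ALPP neighbours that share its sequence are not named, since short reads can be assigned to either.

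The fits were tested on simulated data in which 100 genes per fold were changed. The changed genes had a mean of at least 1 CPM, and all other genes had equal means in all groups. A 1.5-fold change was recovered for 79% of genes in WT cells at 12 h, 75% in knockout cells at 12 h, 66% in the difference between lines at 12 h and 83% between untransfected lines. For a 2-fold change these were 92%, 89%, 81% and 92%, and 13, 8, 6 and 12 unchanged genes were called.

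Alternatives fixed beforehand were relative log expression size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fold of at least 2 beside the adjusted p, the replicate letter as a block, leaving out each replicate in turn, only the compared groups in the fit, and for comparisons within a line all 30 libraries in the fit. Counts were also compared with those from other splits of the same libraries. For comparisons of 2 groups all 10 splits were fitted; for the differences between lines or times, 100 splits were drawn in which DLM and D171N labels were exchanged within a line or a time.

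Gene positions, spans and exon lengths came from GENCODE release v29 for GRCh38, for symbols with a single position; 94.9% of the genes tested in the fit of both lines had a model, with older symbols matched where only 1 was present. Genes are called rarely detected when their mean in untransfected cells was under 0.2 CPM. They were sorted by whether a protein-coding gene of at least 5 CPM in those cells lay within 20 kb on the side of its end, of its start, on both sides or on neither, or within 1 kb and so overlapping. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.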

Results

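STING1 encodes the adaptor that binds cyclic dinucleotides, including the cyclic di-AMP made by dacA, and its mRNA was still present in the line labelled STING knockout. Mean levels in WT cells were 13.2 CPM without transfection, 12.1 CPM with D171N and 11.7 CPM with DLM at 12 h, and 9.69 and 9.74 CPM at 24 h (n = 3 libraries per group). In knockout cells STING1 stood at 9.50 CPM without transfection, 7.18 and 8.25 CPM at 12 h, and 5.98 and 4.75 CPM at 24 h. Single libraries spanned 9.14 to 14.3 CPM in WT and 4.44 to 9.87 CPM in knockout cells. STING1 was lower in untransfected knockout cells than in untransfected WT cells (log2 fold change −0.47 ± 0.098 standard error, edgeR adjusted p = 8.1e-05). An edit that shifts a reading frame can leave an mRNA in place, so these levels do not measure the protein. HEK-Blue ISG cells also carry a secreted alkaline phosphatase reporter behind an interferon-responsive promoter. Reads from such a reporter would be counted with placental alkaline phosphatase, ALPP, and the counts cannot separate it from the gene itself. ALPP stood at 59.0 CPM in untransfected WT cells and at 677 and 816 CPM in WT cells with DLM at 12 and 24 h, against 73.2 and 73.3 CPM with D171N. In knockout cells ALPP was 73.0 CPM without transfection, 72.6 and 59.8 CPM with D171N, and 83.6 and 214 CPM with DLM.

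**Figure D1:**
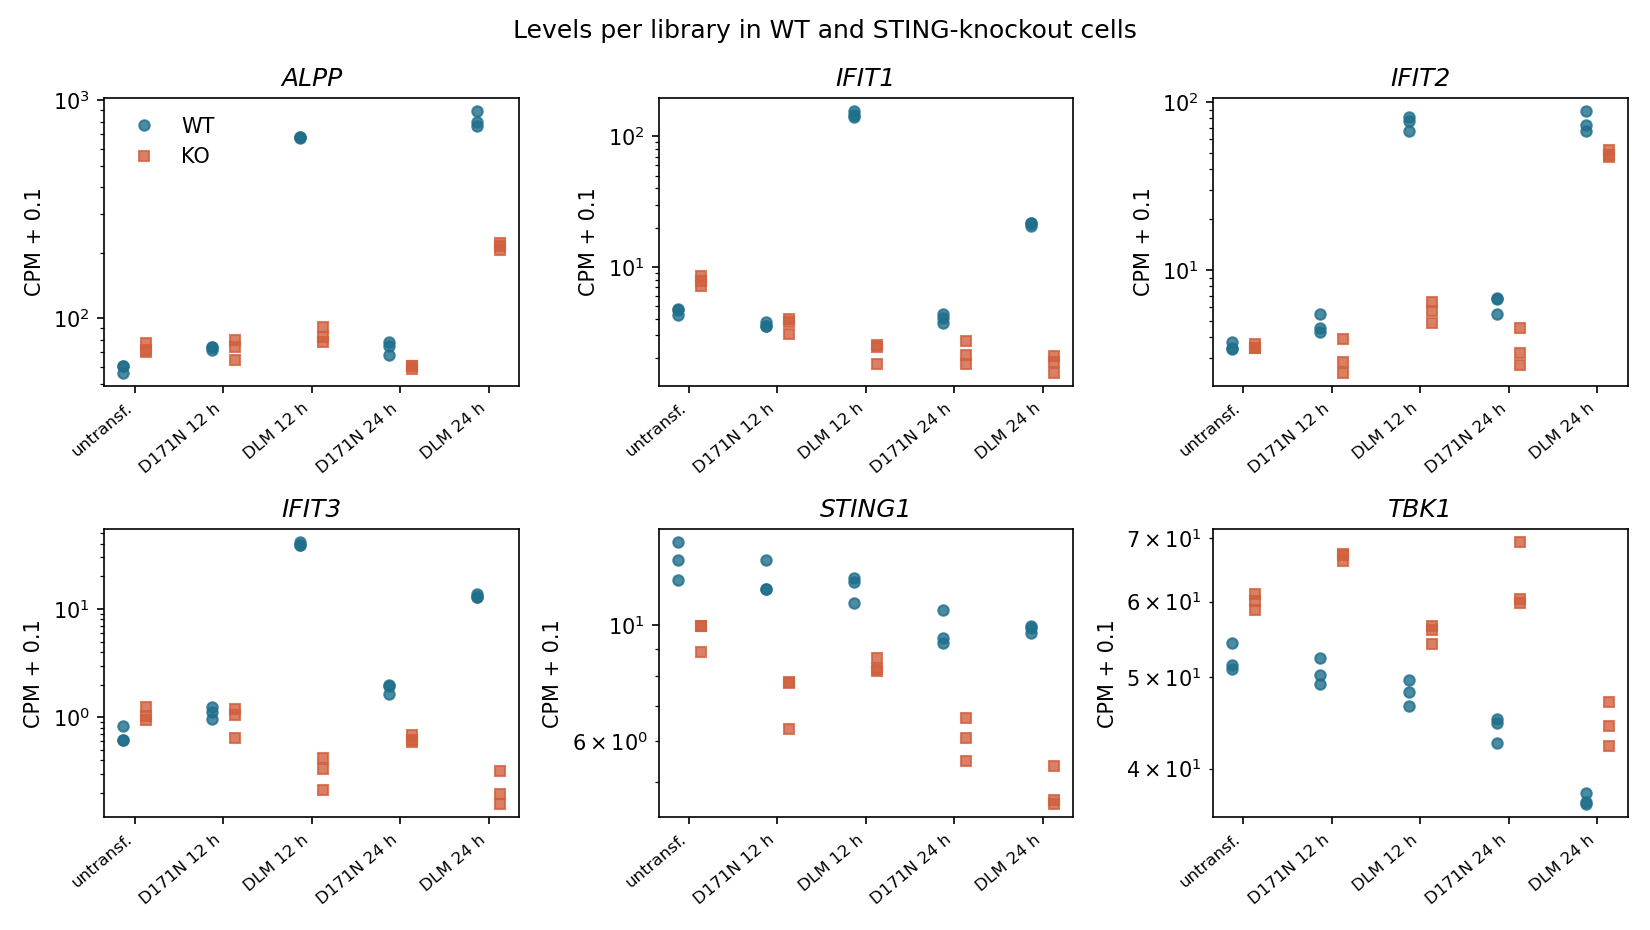
CPM (with 0.1 added for the logarithmic axis) of 6 genes in each of the 30 libraries. Circles are WT and squares knockout libraries, 3 per group. D171N is the catalytically inactive dacA construct and DLM the other dacA construct.

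In WT cells 12 h after transfection, antiviral genes were far higher with DLM than with D171N. IFIT1, whose product binds viral RNA lacking host-type cap methylation, rose by 5.38 ± 0.067 on the log2 scale (adjusted p = 2.1e-40), from 3.52 to 147 CPM. Its neighbours IFIT3 (5.29 ± 0.11) and IFIT2 (4.01 ± 0.14, adjusted p = 9.2e-11) rose as well. So did IFI44 (6.78 ± 0.5, and 8.59 without D171N replicate b), OASL (5.23 ± 0.29), DDX60 (3.37 ± 0.14) and HERC5, the ligase that attaches ISG15 (1.88 ± 0.043). ALPP rose by 3.21 ± 0.051 (adjusted p = 9.3e-31). The cytosolic RNA sensors RIG-I (DDX58, 2.16 ± 0.095), MDA5 (IFIH1, 2.60 ± 0.34, and 3.19 without D171N replicate c) and LGP2 (DHX58, 1.67 ± 0.38) rose too. The kinase TBK1 (−0.07 ± 0.047, adjusted p = 0.26), the transcription factor IRF3 (0.11 ± 0.051, adjusted p = 0.093), STING1 (−0.05 ± 0.085, adjusted p = 0.73) and CGAS (−0.53 ± 0.44, adjusted p = 0.4) did not pass the test, and IFNB1 had too few counts to be tested.

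By group, 15 of the 34 tested interferon-stimulated genes rose at 12 h in WT cells and 1 fell (16 and 1 when adjusted over the list alone; camera adjusted p = 5.6e-45, and adjusted p = 5.4e-06 with an estimated correlation). Of the 6 tested members of the list of interferons and IRF3-induced chemokines, 4 rose and 1, ATF3, fell (4 and 1 adjusted over the list alone). Camera gave adjusted p = 4e-40 for this list, and adjusted p = 5.4e-06 with an estimated correlation. Its tested members include IFIT1, IFIT2, ISG15, PMAIP1 and ATF3, which are neither interferons nor chemokines. IFIT1, IFIT2 and ISG15 are also in the list of interferon-stimulated genes. Stress-response genes were lower with DLM than with D171N, which itself raised them against untransfected cells. None of the 31 ATF4 and amino acid response genes rose and 21 fell (23 adjusted over the list alone; adjusted p = 3.5e-14, and adjusted p = 0.0039 with an estimated correlation). Among these were CHAC1, which degrades glutathione (−1.06 ± 0.16), ATF3 (−1.05 ± 0.05) and DDIT4 (−1.20 ± 0.15). Of 29 immediate early genes, 19 fell and 0 rose (19 and 0 adjusted over the list alone; adjusted p = 1.2e-14, and adjusted p = 0.021 with an estimated correlation). JUN (−0.94 ± 0.037), DUSP1 (−0.91 ± 0.051), JUND (−0.59 ± 0.056) and MYC (−0.40 ± 0.043) were among them. Replication genes such as GINS3 (−0.48 ± 0.044) and MCM10 (−0.34 ± 0.04) were lower. Of 30 S-phase genes, 17 were down and 1 was up (18 and 2 adjusted over the list alone; adjusted p = 1.6e-05, but adjusted p = 0.18 with an estimated correlation). The metalloprotease MMP14 rose (2.06 ± 0.27), while TENT5B (−1.43 ± 0.28) and the platelet-activating factor receptor PTAFR (−1.35 ± 0.24) fell. In all, edgeR called 5645 of 19368 genes, 2590 up and 3055 down, of which 439 and 47 changed by at least 2-fold. With DESeq2 the genes up were 1619. The labels do not say whether replicates are separate cultures, so p-values here measure only the spread between these samples.

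Smaller shifts at 12 h in WT cells covered other lists. Of 18 genes of antigen presentation by MHC class I, 7 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.016, but adjusted p = 0.23 with an estimated correlation). B2M rose by 0.18 ± 0.041. In the unfolded protein response of the endoplasmic reticulum, 12 of 28 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.0053, but adjusted p = 0.23 with an estimated correlation). Ribosomal protein mRNAs rose in 32 of 42 cases (36 adjusted over the list alone; adjusted p = 1.7e-10, but adjusted p = 0.26 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes did so in 18 of 41 (20 adjusted over the list alone; adjusted p = 2.2e-05, but adjusted p = 0.26 with an estimated correlation), with 0 falling in either. Hypoxia-response genes fell in 12 of 27 cases and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.00057, but adjusted p = 0.18 with an estimated correlation). Heat shock genes fell in 6 of 20 and rose in 1 (6 and 3 adjusted over the list alone; adjusted p = 0.048, but adjusted p = 0.57 with an estimated correlation). HSPA8 fell by 0.37 ± 0.039. Of 23 NF-kB targets 6 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 0.065). NFKB1 was among them (−0.26 ± 0.058). The set test was not passed by p53 targets (2 of 24 up, 9 down; 3 and 9 adjusted over the list alone; adjusted p = 0.055) or G2 and mitosis genes (6 of 30 up, 1 down; 6 and 1 adjusted over the list alone; adjusted p = 0.079). NRF2 oxidative stress genes did not pass either (2 of 23 up, 4 down; 2 and 4 adjusted over the list alone; adjusted p = 0.57). Among these, heme oxygenase HMOX1 fell by 0.61 ± 0.052. Cholesterol biosynthesis genes rose in 4 of 25 cases and fell in 5 (5 and 6 adjusted over the list alone, adjusted p = 0.61), with a median of −0.0319 and a mean of 0.000884. Nucleic acid sensors rose in 2 of 17 and fell in 2 (2 and 2 adjusted over the list alone, adjusted p = 0.98), with a median of −0.0469 and a mean of 0.159. DDX58 stands under its newer name RIGI in this list and in that of interferon-stimulated genes, was not matched to the tables there, and is missing from the tallies of both. Replication-dependent histones, read as a sign of non-polyadenylated RNA, rose in 6 of 22 cases and fell in 2 (7 and 3 adjusted over the list alone; adjusted p = 0.19).

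By 24 h in WT cells the difference between DLM and D171N covered most expressed genes, and by fold the antiviral genes no longer led it. Among the largest rises were genes under 1 CPM in untransfected cells: the intestinal stress sensor ERN2 (5.01 ± 0.26), MROH2A (4.71 ± 0.32), WDR38 (4.33 ± 0.36), ITGB1BP2 (4.08 ± 0.25), SPACA4 (3.84 ± 0.36) and glycerol-3-phosphate dehydrogenase GPD1 (3.74 ± 0.19). IFIT2 was still higher by 3.58 ± 0.13 (adjusted p = 2.6e-12), IFI44 by 3.51 ± 0.3, ALPP by 3.47 ± 0.051 (adjusted p = 1.4e-31), IFIT3 by 2.90 ± 0.12, IFIT1 by 2.41 ± 0.084, IFI6 by 2.09 ± 0.091 and HERC5 by 1.36 ± 0.044. Among the largest falls were SOX30 (−3.83 ± 0.25), the ubiquitin ligase RNF144B (−3.16 ± 0.19), the fractalkine receptor CX3CR1 (−3.09 ± 0.35), ZBTB7C (−2.93 ± 0.26), the natriuretic peptide clearance receptor NPR3 (−2.91 ± 0.24), the mitochondrial co-activator PPARGC1A (−2.89 ± 0.34) and ZNF536 (−2.65 ± 0.13). CGAS fell (−1.70 ± 0.33) at low levels, from 1.66 to 0.503 CPM, and TBK1 by 0.26 ± 0.05; STING1 gave 0.01 ± 0.094 (adjusted p = 0.95).

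Among the lists at 24 h in WT cells, all 42 ribosomal protein genes rose (42 adjusted over the list alone; adjusted p = 1.2e-44, but adjusted p = 0.057 with an estimated correlation). RPL7 rose by 1.04 ± 0.04. Of 41 oxidative phosphorylation genes, 40 rose and 0 fell (40 and 1 adjusted over the list alone; adjusted p = 1.3e-16, but adjusted p = 0.057 with an estimated correlation). COX6C rose by 0.97 ± 0.049. Antigen presentation rose in 13 of 18 cases and fell in 0 (13 and 0 adjusted over the list alone; adjusted p = 3.5e-05, but adjusted p = 0.057 with an estimated correlation). B2M rose by 0.89 ± 0.041 and HLA-C by 0.89 ± 0.042. ATF4 targets fell in 22 of 31 cases and rose in 2 (22 and 3 adjusted over the list alone; adjusted p = 1.3e-06, but adjusted p = 0.057 with an estimated correlation). p53 targets fell in 17 of 24 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.011, but adjusted p = 0.057 with an estimated correlation). AEN (−1.37 ± 0.046) and PPM1D (−1.17 ± 0.039) fell. Immediate early genes fell in 17 of 29 cases and rose in 5 (17 and 5 adjusted over the list alone; adjusted p = 0.00056, but adjusted p = 0.22 with an estimated correlation). JUN (−1.47 ± 0.038) and DUSP1 (−1.65 ± 0.055) fell. S-phase genes fell in 22 of 30 cases and rose in 5 (22 and 5 adjusted over the list alone; adjusted p = 3.5e-05, but adjusted p = 0.22 with an estimated correlation). MCM10 fell by 1.47 ± 0.043. Interferon-stimulated genes now split into 16 up and 10 down of 34 (16 and 10 adjusted over the list alone; adjusted p = 0.0086, but adjusted p = 0.17 with an estimated correlation). The unfolded protein response split as well, 16 up and 10 down of 28 (16 and 10 adjusted over the list alone; adjusted p = 0.12). The chaperone HSP90B1 (1.17 ± 0.041) and the disulfide isomerase PDIA3 (0.93 ± 0.042) rose while the transcription factors XBP1 (−1.11 ± 0.049) and ATF6 (−0.82 ± 0.041) fell. NF-kB targets fell in 16 of 23 cases and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.16). TNFAIP3 fell by 1.51 ± 0.14. edgeR called 13835 of 19368 genes, 6542 up and 7293 down, with 1783 and 1920 changed by at least 2-fold. The median change over all tested genes was −0.0304. As in every comparison here, changes are relative to the other genes, since TMM, relative log expression and DESeq2 scaling all assume a stable typical gene. A change in total mRNA per cell was not measured, so rises and falls of whole lists are not absolute amounts.

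Markers of other cell types were few and near the floor in WT cells at 24 h. Of 4 tested leukocyte and monocyte markers 3 rose and 1 fell (3 and 1 adjusted over the list alone): CSF1R by 1.79 ± 0.36 (2.40 without D171N replicate b), CORO1A by 0.69 ± 0.16, CD14 by 0.66 ± 0.19 and ITGAM by −1.30 ± 0.26. Of 4 fibroblast and keratinocyte markers 2 rose and 1 fell among all genes tested, where KRT17 gave 2.27 ± 0.35 and PDGFRA −1.12 ± 0.19 (3 and 1 adjusted over the list alone). The 13 mitochondrially encoded mRNAs had no counts in any library, so 0 were tested with edgeR at either threshold.

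The DLM effect in WT cells differed between 24 h and 12 h for 9629 genes (edgeR, 3871 up and 5758 down, with 539 and 975 by at least 2-fold). Antiviral genes were among those whose rise had shrunk: IFIT1 by −2.98 ± 0.13 (adjusted p = 7.4e-20), IFIT3 by −2.39 ± 0.2 and HERC5 by −0.52 ± 0.062. ALPP changed little more (0.26 ± 0.069, adjusted p = 0.0019). MROH2A (3.62 ± 0.77), ITGB1BP2 (2.54 ± 0.45) and the serine protease PRSS8 (2.47 ± 0.46) gained with time, and SOX30 (−2.88 ± 0.39), RNF144B (−2.53 ± 0.25) and CX3CR1 (−2.48 ± 0.52) lost. All 42 ribosomal protein genes gained (42 adjusted over the list alone; adjusted p = 4.2e-55, but adjusted p = 0.058 with an estimated correlation). RPLP0 gained 0.84 ± 0.052. Of 18 antigen presentation genes 11 gained and 0 lost (11 and 0 adjusted over the list alone; adjusted p = 1.7e-05, but adjusted p = 0.058 with an estimated correlation). HLA-C gained 0.77 ± 0.059. Interferon-stimulated genes lost in 15 of 34 cases and gained in 4 (15 and 5 adjusted over the list alone; adjusted p = 0.097).

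In knockout cells at 12 h IFIT1, IFIT3 and HERC5, which DLM raised in WT cells, were not higher, and IFIT2 rose only slightly. IFI44, OASL and IFIH1 did not pass the filter on counts in knockout cells and were not tested there. ATF4 targets and immediate early genes were lower than with D171N, as in WT cells. IFIT1 stood at 2.16 CPM with DLM and 3.53 CPM with D171N, IFIT3 at 0.221 and 0.856 CPM, and HERC5 at 38.3 and 45.9 CPM. IFIT2 rose (adjusted p = 7.3e-05) from 2.98 to 5.58 CPM, and IFIT5 fell by 0.60 ± 0.077. ATF3 (−0.94 ± 0.066), CHAC1 (−1.10 ± 0.24), JUN (−0.83 ± 0.046) and DUSP1 (−0.89 ± 0.069) fell. XBP1 (−0.54 ± 0.07), HERPUD1 (−0.40 ± 0.069) and the chaperone HSPA5 (−0.24 ± 0.052) fell too, but the unfolded protein response as a list did not pass (2 of 28 up and 6 down, and 3 and 6 adjusted over the list alone, adjusted p = 0.086). Among the largest rises were genes under 1 CPM in untransfected cells: ITGB1BP2 (2.91 ± 0.32), the potassium channel subunit KCNS1 (2.60 ± 0.39), SHISA7 (2.49 ± 0.38), CCDC17 (2.49 ± 0.23), the retinol dehydrogenase RDH5 (1.95 ± 0.37) and the tyrosine kinase FES (1.81 ± 0.36). RGS4 fell by 1.37 ± 0.24 and TBK1 by 0.25 ± 0.063; STING1 gave 0.19 ± 0.14 (adjusted p = 0.33).

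Of 28 interferon-stimulated genes tested in knockout cells at 12 h, 3 rose and 5 fell (3 and 5 adjusted over the list alone, adjusted p = 0.85). Their median was 0.0704 and their mean −0.0371. ATF4 targets fell in 20 of 30 cases and rose in 0 (23 and 0 adjusted over the list alone; adjusted p = 2.7e-11, and adjusted p = 0.029 with an estimated correlation). Immediate early genes fell in 16 of 27 (17 down and 1 up adjusted over the list alone; adjusted p = 4.2e-10, and adjusted p = 0.029 with an estimated correlation). p53 targets fell in 9 of 23 and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.038 with an estimated correlation). Ribosomal protein genes rose in 40 of 42 cases (40 adjusted over the list alone; adjusted p = 3.1e-17, but adjusted p = 0.26 with an estimated correlation). RPL27 rose by 0.35 ± 0.058 and the ATP synthase gene ATP5MC1 by 0.43 ± 0.067. edgeR called 4592 of 16879 genes, 2108 up and 2484 down, with 575 and 38 changed by at least 2-fold. Without DLM replicate b the genes up were 1350.

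At 24 h in knockout cells, IFIT2 rose by 3.92 ± 0.13 (adjusted p = 2.3e-26), from 3.39 to 49.0 CPM, and ALPP by 1.85 ± 0.06 (adjusted p = 4.3e-26), from 59.8 to 214 CPM. IFIT1 stood at 1.74 CPM, against 2.11 CPM with D171N, and HERC5 at 38.4 CPM. DHX58 rose by 3.66 ± 0.49 and ISG15 by 1.01 ± 0.11, while IFIT5 (−1.69 ± 0.082) and the nuclear body gene PML (−0.69 ± 0.075) fell. Genes under 1 CPM in untransfected cells were again among the largest rises, such as MROH2A (5.98 ± 0.39), ERN2 (5.49 ± 0.38), WDR38 (4.87 ± 0.37), SPACA4 (4.66 ± 0.41), FAM83E (4.38 ± 0.25) and PRSS8 (4.28 ± 0.42). SOX30 (−3.37 ± 0.45), ZNF536 (−3.16 ± 0.18), RNF144B (−3.13 ± 0.21), the Notch co-activator MAML2 (−2.90 ± 0.21) and the ephrin receptor EPHB1 (−2.86 ± 0.15) fell. STING1 passed the test with −0.33 ± 0.14 (adjusted p = 0.038), a call that ended without D171N replicate a (−0.34) or c (−0.27) and without DLM replicate a (−0.27) or b (−0.29). It ended too with relative log expression size factors (−0.30) and with DESeq2 (−0.32).

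The lists of knockout cells at 24 h again showed every ribosomal protein gene higher with DLM (42 of 42, and 42 adjusted over the list alone; adjusted p = 1.7e-57, but adjusted p = 0.071 with an estimated correlation). RPL7A rose by 1.41 ± 0.052. Oxidative phosphorylation genes rose in 39 of 41 cases and fell in 1 (39 and 1 adjusted over the list alone; adjusted p = 3.2e-16, but adjusted p = 0.14 with an estimated correlation). COX7B rose by 1.20 ± 0.052. Antigen presentation rose in 13 of 16 and fell in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.00012, but adjusted p = 0.12 with an estimated correlation). HLA-C rose by 1.12 ± 0.054. ATF4 targets fell in 21 of 30 cases and rose in 5 (21 and 5 adjusted over the list alone; adjusted p = 0.00034, but adjusted p = 0.24 with an estimated correlation). p53 targets fell in 17 of 23 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.0013, but adjusted p = 0.071 with an estimated correlation). S-phase genes fell in 22 of 30 and rose in 7 (22 and 7 adjusted over the list alone; adjusted p = 0.0012, but adjusted p = 0.55 with an estimated correlation). MCM10 fell by 1.45 ± 0.052. XBP1 (−1.26 ± 0.066), ATF6 (−1.04 ± 0.047), JUN (−1.49 ± 0.046) and HMOX1 (−1.74 ± 0.08) fell and HSP90B1 (1.12 ± 0.047) rose. Interferon-stimulated genes did not pass the set test (7 of 28 up and 11 down, and 7 and 11 adjusted over the list alone, adjusted p = 0.79). Their median was −0.113 and their mean 0.0332. edgeR called 12437 of 16879 genes, 5957 up and 6480 down, with 2051 and 2053 changed by at least 2-fold.

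With time, the DLM effect in knockout cells changed for 8222 genes (edgeR, 3332 up and 4890 down, with 599 and 1032 by at least 2-fold). IFIT2 gained 2.92 ± 0.23 between 12 h and 24 h (adjusted p = 1.7e-13) and ALPP 1.64 ± 0.087 (adjusted p = 8.5e-18). FAM83E (3.18 ± 0.58) and the muscle ubiquitin ligase TRIM54 (2.82 ± 0.74) gained too, while FBXO36 (−2.90 ± 0.48) lost. All 42 ribosomal protein genes gained (42 adjusted over the list alone; adjusted p = 1.1e-73, but adjusted p = 0.06 with an estimated correlation). RPS18 gained 1.16 ± 0.072. Of 16 antigen presentation genes 10 gained and 0 lost (11 and 0 adjusted over the list alone; adjusted p = 6.5e-06, but adjusted p = 0.06 with an estimated correlation). B2M gained 0.87 ± 0.069. Of 28 interferon-stimulated genes 5 gained and 7 lost (5 and 7 adjusted over the list alone; adjusted p = 0.71), a balance that turned to 5 and 4 with DESeq2; their median was −0.113 and their mean 0.0703.

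Much of the DLM effect was shared by the 2 lines. Among 16833 genes tested in both, the log2 changes correlated with Pearson r = 0.691 at 12 h and 0.933 at 24 h. At 12 h, 1313 genes rose in both lines (307 for independent lists) and 1828 fell in both (447); 8 rose in WT and fell in knockout cells, and 2 did the opposite. At 24 h, 5253 rose in both (2096 for independent lists), 6010 fell in both (2641), 10 rose in WT and fell in knockout cells and 16 did the opposite. RNF144B, SOX30 and ZNF536 were among the shared falls at 24 h, and MROH2A, ERN2 and WDR38 among the shared rises.

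**Figure D2:**
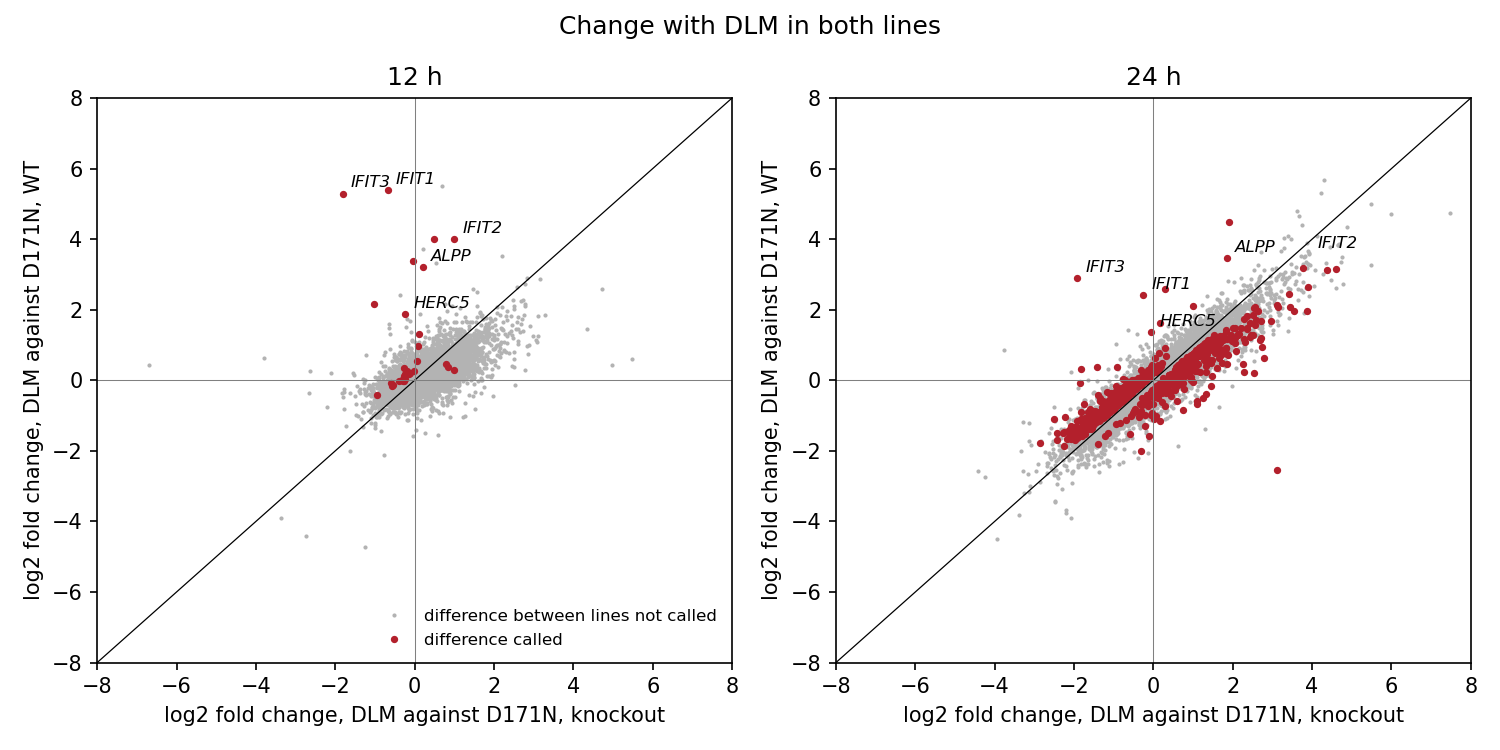
Change with DLM against D171N in knockout cells (horizontal) and WT cells (vertical) at 12 h and 24 h, on the log2 scale from edgeR. Each point is a gene tested in both lines. Red points passed the test of the difference between lines at an adjusted p under 0.05, and the diagonal marks equal change.

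Most of the largest differences between the lines at 12 h lay in antiviral genes and ALPP. The DLM effect was larger in WT than in knockout cells for IFIT3 (difference 7.11 ± 0.46, adjusted p = 2.7e-18), IFIT1 (6.08 ± 0.21, adjusted p = 3.2e-31), DDX60 (3.44 ± 0.44), DDX58 (3.20 ± 0.19), ALPP (3.02 ± 0.084, adjusted p = 3.2e-31), IFIT2 (3.02 ± 0.27), HERC5 (2.13 ± 0.084) and IFI6 (1.23 ± 0.2). For IFIT3, part of the difference came from lower knockout levels with DLM, 0.111 to 0.319 CPM against 0.538 to 1.09 CPM with D171N. Other genes that differed included PMAIP1, which encodes the pro-apoptotic protein NOXA (0.62 ± 0.063), and the endoplasmic reticulum chaperone HSPA5 (0.44 ± 0.066). In the lists, 8 of 33 interferon-stimulated genes differed upward and 0 downward (11 and 0 adjusted over the list alone; adjusted p = 2.2e-38, and adjusted p = 1.2e-07 with an estimated correlation). The same held for 3 of 6 tested members of the list of interferons and IRF3-induced chemokines (4 adjusted over the list alone, camera adjusted p = 8.8e-53, and adjusted p = 1.4e-10 with an estimated correlation). It held too for 4 of 28 genes of the unfolded protein response (11 adjusted over the list alone; adjusted p = 2.3e-15, and adjusted p = 0.0071 with an estimated correlation). STING1 gave −0.21 ± 0.15 (adjusted p = 0.77). edgeR called 30 of 19901 genes, 27 up and 3 down, with 1668 at an unadjusted p under 0.05. The count was 19 with only the compared groups in the fit, 80 without knockout D171N replicate a and 17 without replicate c of that group. The 3 genes down became 21 without that replicate a, 10 without knockout DLM replicate a, and 0 without knockout DLM replicate b or with only the compared groups. They became 5 with no filter on low counts, and 1 without WT D171N replicate b or c, WT DLM replicate b or c, or knockout D171N replicate c.

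At 24 h the lines differed in 1210 genes (745 up and 465 down in WT relative to knockout cells, with 21 and 62 by at least 2-fold), and the antiviral genes were still among them. IFIT3 (4.84 ± 0.52, and 5.65 without knockout DLM replicate a), IFIT1 (2.68 ± 0.22, adjusted p = 4.2e-13), ALPP (1.64 ± 0.081, adjusted p = 1.9e-20), HERC5 (1.43 ± 0.082) and IFI6 (1.11 ± 0.19) kept a larger DLM effect in WT cells. DDX58 (1.79 ± 0.21) differed in the same direction, but this difference came with a fall of DDX58 in knockout cells. Part of the IFIT3 difference also came from a fall there (log2 change −1.93, edgeR adjusted p = 0.0046), at 1 to 4 counts per library with DLM. IFIT2, chosen after its values were seen, gave −0.32 ± 0.199 (adjusted p = 0.397). The mitotic genes CDK1 (0.38 ± 0.068) and CCNB1 (0.33 ± 0.067) and the p53 target ZMAT3 (0.45 ± 0.091) were also higher by this measure. Lower were CPNE7 (−1.57 ± 0.36), LRRN2 (−1.46 ± 0.36), the histone gene H4C5 (−1.01 ± 0.2), RPS18 (−0.38 ± 0.067) and RPLP0 (−0.38 ± 0.067). Interferon-stimulated genes differed upward in 9 of 33 cases and downward in 1 (11 and 2 adjusted over the list alone; adjusted p = 1.6e-07, and adjusted p = 0.0087 with an estimated correlation). Ribosomal protein genes differed downward in 34 of 42 cases and upward in 0 (41 and 0 adjusted over the list alone; adjusted p = 6.4e-40, but adjusted p = 0.052 with an estimated correlation). p53 targets differed upward in 8 of 24 cases and downward in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0051, and adjusted p = 0.019 with an estimated correlation). G2 and mitosis genes did so in 6 of 30 (7 adjusted over the list alone; adjusted p = 4.1e-05, but adjusted p = 0.19 with an estimated correlation). The count of 1210 was 742 with no filter on low counts (321 up and 421 down), 787 without knockout DLM replicate a and 764 without WT DLM replicate b. The genes down were 255 and 266 in the last 2 cases, 307 without knockout D171N replicate a, 306 without WT DLM replicate c and 265 with only the compared groups in the fit.

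Transfection with the inactive D171N construct itself raised ATF4 targets and immediate early genes against untransfected cells in both lines. In WT cells at 12 h, the stress transcription factor ATF3 rose by 1.78 ± 0.053 (adjusted p = 1.9e-22), HMOX1 by 1.74 ± 0.058 and the cystine transporter SLC7A11 by 1.57 ± 0.1. ETV5 (1.83 ± 0.17), FOS (1.62 ± 0.12), EGR1 (1.44 ± 0.1) and STC2 (1.25 ± 0.068) rose too. NEURL1B (−1.22 ± 0.15) and the sugar transporter SLC2A12 (−1.03 ± 0.097) fell. ATF4 targets rose in 22 of 31 cases and fell in 2 (24 and 2 adjusted over the list alone; adjusted p = 2.3e-34, and adjusted p = 0.00029 with an estimated correlation). Immediate early genes rose in 17 of 29 and fell in 1 (17 and 1 adjusted over the list alone; adjusted p = 1.2e-13, and adjusted p = 0.036 with an estimated correlation). At 24 h in WT cells ATF3 reached 2.77 ± 0.053 and SLC7A11 2.73 ± 0.094. ZNF619 (4.48 ± 0.26), CPNE7 (4.47 ± 0.31), CASS4 (4.14 ± 0.23) and CGAS (3.51 ± 0.41) rose as well. ATF4 targets rose in 27 of 31 cases and fell in 2 (27 and 2 adjusted over the list alone; adjusted p = 7.1e-32, and adjusted p = 0.00051 with an estimated correlation). Replication-dependent histones rose in 17 of 22 and fell in 2 (18 and 2 adjusted over the list alone; adjusted p = 7.7e-09, and adjusted p = 0.0039 with an estimated correlation). H4C5 rose by 3.28 ± 0.14 and H4C8 by 2.56 ± 0.098. Immediate early genes rose in 17 of 29 cases and fell in 3 (17 and 3 adjusted over the list alone; adjusted p = 3.7e-05, but adjusted p = 0.24 with an estimated correlation). Mitotic genes fell in 20 of 30 cases and rose in 2 (20 and 2 adjusted over the list alone; adjusted p = 9.8e-07, but adjusted p = 0.1 with an estimated correlation). CDK1 fell by 0.73 ± 0.041. Cholesterol synthesis genes fell in 17 of 25 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 3.7e-05, but adjusted p = 0.17 with an estimated correlation). INSIG1 fell by 0.64 ± 0.038. Heat shock genes fell in 16 of 20 cases and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 3.7e-05, but adjusted p = 0.38 with an estimated correlation). STING1 gave −0.13 ± 0.084 (adjusted p = 0.28) at 12 h and fell by 0.43 ± 0.085 (adjusted p = 3.1e-05) at 24 h. edgeR called 5316 genes at 12 h (2474 up, 2842 down) and 11724 at 24 h (6065 up, 5659 down) of 19368. At 2-fold or more these were 232 up and 41 down, and 1857 and 169. The 24 h balance turned to 5683 up and 6052 down with relative log expression size factors and to 4744 and 5547 with DESeq2, and to 5475 and 5738 with all 30 libraries in the fit. That at 12 h turned to 3068 and 3051 with only the compared groups in the fit. There is no mock-transfected control and the untransfected libraries carry no time, so these values combine transfection, the inactive protein and time in culture.

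In knockout cells D171N also raised ATF4 targets. At 12 h HMOX1 rose by 1.99 ± 0.083, SLC7A11 by 1.94 ± 0.11, CHAC1 by 1.82 ± 0.24 and ATF3 by 1.58 ± 0.066, with XBP1 (0.62 ± 0.067) and HSPA5 (0.44 ± 0.051). ATF4 targets rose in 18 of 30 cases and fell in 0 (19 and 0 adjusted over the list alone; adjusted p = 2.3e-34, and adjusted p = 0.00091 with an estimated correlation). Immediate early genes rose in 10 of 27 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 3.1e-09, and adjusted p = 0.027 with an estimated correlation). The unfolded protein response rose in 9 of 28 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 6.4e-09, but adjusted p = 0.07 with an estimated correlation). IFIT1 fell by 1.13 ± 0.17. Interferon-stimulated genes fell in 6 of 28 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.027 with an estimated correlation). In WT cells at 12 h that list did not pass (2 of 34 up and 7 down, and 2 and 8 adjusted over the list alone, adjusted p = 0.21). The list of interferons and IRF3-induced chemokines, which holds ATF3, went the other way with D171N. By camera with the replicate block it was up in knockout cells at 12 h (adjusted p = 1.3e-05) and 24 h (adjusted p = 6e-05). In WT cells it was up as well (camera adjusted p = 3.2e-11 and 1.6e-09). At 24 h in knockout cells ATF3 (2.47 ± 0.065), SLC7A11 (3.12 ± 0.11) and ZNF619 (4.37 ± 0.44) rose. IFIT1 (−1.84 ± 0.19), NEURL1B (−1.66 ± 0.23) and GALNT12 (−1.50 ± 0.19) fell. ATF4 targets rose in 27 of 30 cases and fell in 1 (27 and 1 adjusted over the list alone; adjusted p = 7.8e-33, and adjusted p = 0.0027 with an estimated correlation). Histones rose in 14 of 18 cases and fell in 1 (14 and 2 adjusted over the list alone; adjusted p = 6.5e-07, and adjusted p = 0.0045 with an estimated correlation). H2AC6 rose by 2.08 ± 0.12. Immediate early genes rose in 13 of 27 cases and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0001, but adjusted p = 0.13 with an estimated correlation). Heat shock genes fell in 15 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.00025, but adjusted p = 0.33 with an estimated correlation). STING1 fell by 0.66 ± 0.13 (adjusted p = 4.7e-05) and ALPP by 0.28 ± 0.063 at 24 h. edgeR called 3398 genes at 12 h (1615 up, 1783 down) and 8875 at 24 h (4641 up, 4234 down) of 16879. At 2-fold or more these were 156 up and 26 down, and 1245 and 116. The first count was 2091 without untransfected replicate b (990 up, 1101 down), and its balance turned to 1483 up and 1459 down with only the compared groups in the fit and to 1402 and 1326 without D171N replicate a. The 24 h balance turned to 4248 up and 4711 down with relative log expression size factors and to 3537 and 4238 with DESeq2.

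Against untransfected cells, DLM in WT cells at 12 h raised OASL by 6.62 ± 0.36, IFIT3 by 6.04 ± 0.12, IFI44 by 5.92 ± 0.45, IFIT1 by 5.03 ± 0.066 and IFIT2 by 4.45 ± 0.15. It lowered the sphingosine phosphate receptor S1PR5 (−1.54 ± 0.26), ELFN1 (−1.50 ± 0.27) and PLEKHA2 (−1.49 ± 0.16). All 6 tested members of the list of interferons and IRF3-induced chemokines rose (6 adjusted over the list alone, camera adjusted p = 2.6e-55, and adjusted p = 1.7e-06 with an estimated correlation). Most of these members, such as IFIT1, IFIT2 and ATF3, are neither interferons nor chemokines. D171N alone had raised this list at 12 h too (camera with the replicate block, adjusted p = 3.2e-11), with ATF3 among its members. The unfolded protein response rose in 20 of 28 cases and fell in 3 (21 and 3 adjusted over the list alone; adjusted p = 7.9e-09, and adjusted p = 0.035 with an estimated correlation). HSPA5 rose by 0.46 ± 0.038. Of 31 ATF4 targets 13 rose and 4 fell (13 and 4 adjusted over the list alone; adjusted p = 0.0014, but adjusted p = 0.14 with an estimated correlation). Histones rose in 7 of 22 and fell in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.048, but adjusted p = 0.14 with an estimated correlation). At 24 h IFI44 rose by 6.19 ± 0.45. RTN4RL1 (−3.85 ± 0.24), RNF144B (−3.37 ± 0.19) and PRAG1 (−3.02 ± 0.14) fell. S-phase genes fell in 25 of 30 cases and rose in 3 (25 and 3 adjusted over the list alone; adjusted p = 1.9e-08, but adjusted p = 0.15 with an estimated correlation). Among ATF4 targets 16 of 31 rose and 7 fell (16 and 7 adjusted over the list alone; adjusted p = 0.012, but adjusted p = 0.23 with an estimated correlation). Histones rose in 19 of 22 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 0.0039, but adjusted p = 0.14 with an estimated correlation). In knockout cells at 12 h, CCDC17 (3.52 ± 0.26), the coagulation protein gene PROZ (3.20 ± 0.32) and the invariant chain gene CD74 (3.07 ± 0.39) rose. IFIT1 (−1.81 ± 0.21) and ZBTB7C (−1.67 ± 0.37) fell. S-phase genes fell in 24 of 30 cases (24 adjusted over the list alone; adjusted p = 3.9e-09, but adjusted p = 0.28 with an estimated correlation). Of 30 ATF4 targets 9 rose and 3 fell (10 and 3 adjusted over the list alone; adjusted p = 0.0046, but adjusted p = 0.3 with an estimated correlation). Histones rose in 6 of 18 and fell in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.024, but adjusted p = 0.13 with an estimated correlation). At 24 h WDR38 (6.93 ± 0.47), FAM83E (6.19 ± 0.32), IFIT2 (3.85 ± 0.13) and ALPP (1.57 ± 0.059) rose. EPHB1 (−3.26 ± 0.14), EMILIN3 (−3.17 ± 0.1) and STING1 (−0.98 ± 0.13) fell. Among ATF4 targets 16 of 30 rose and 8 fell (16 and 8 adjusted over the list alone; adjusted p = 0.014, but adjusted p = 0.34 with an estimated correlation). Histones rose in 17 of 18 and fell in 0 (17 and 0 adjusted over the list alone; adjusted p = 0.002, but adjusted p = 0.1 with an estimated correlation). edgeR called 8048 genes in WT cells at 12 h (3836 up, 4212 down), 14217 at 24 h (7268 up, 6949 down). It called 5590 in knockout cells at 12 h (2637 up, 2953 down) and 12566 at 24 h (6514 up, 6052 down). At 2-fold or more these were 908 up and 74 down, 2978 and 1918, 987 and 101, and 2712 and 1907. With DESeq2 the genes up in WT cells at 12 h were 2281. With only the compared groups in the fit the balance in knockout cells at 12 h turned to 3126 and 3048.

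**Figure D3:**
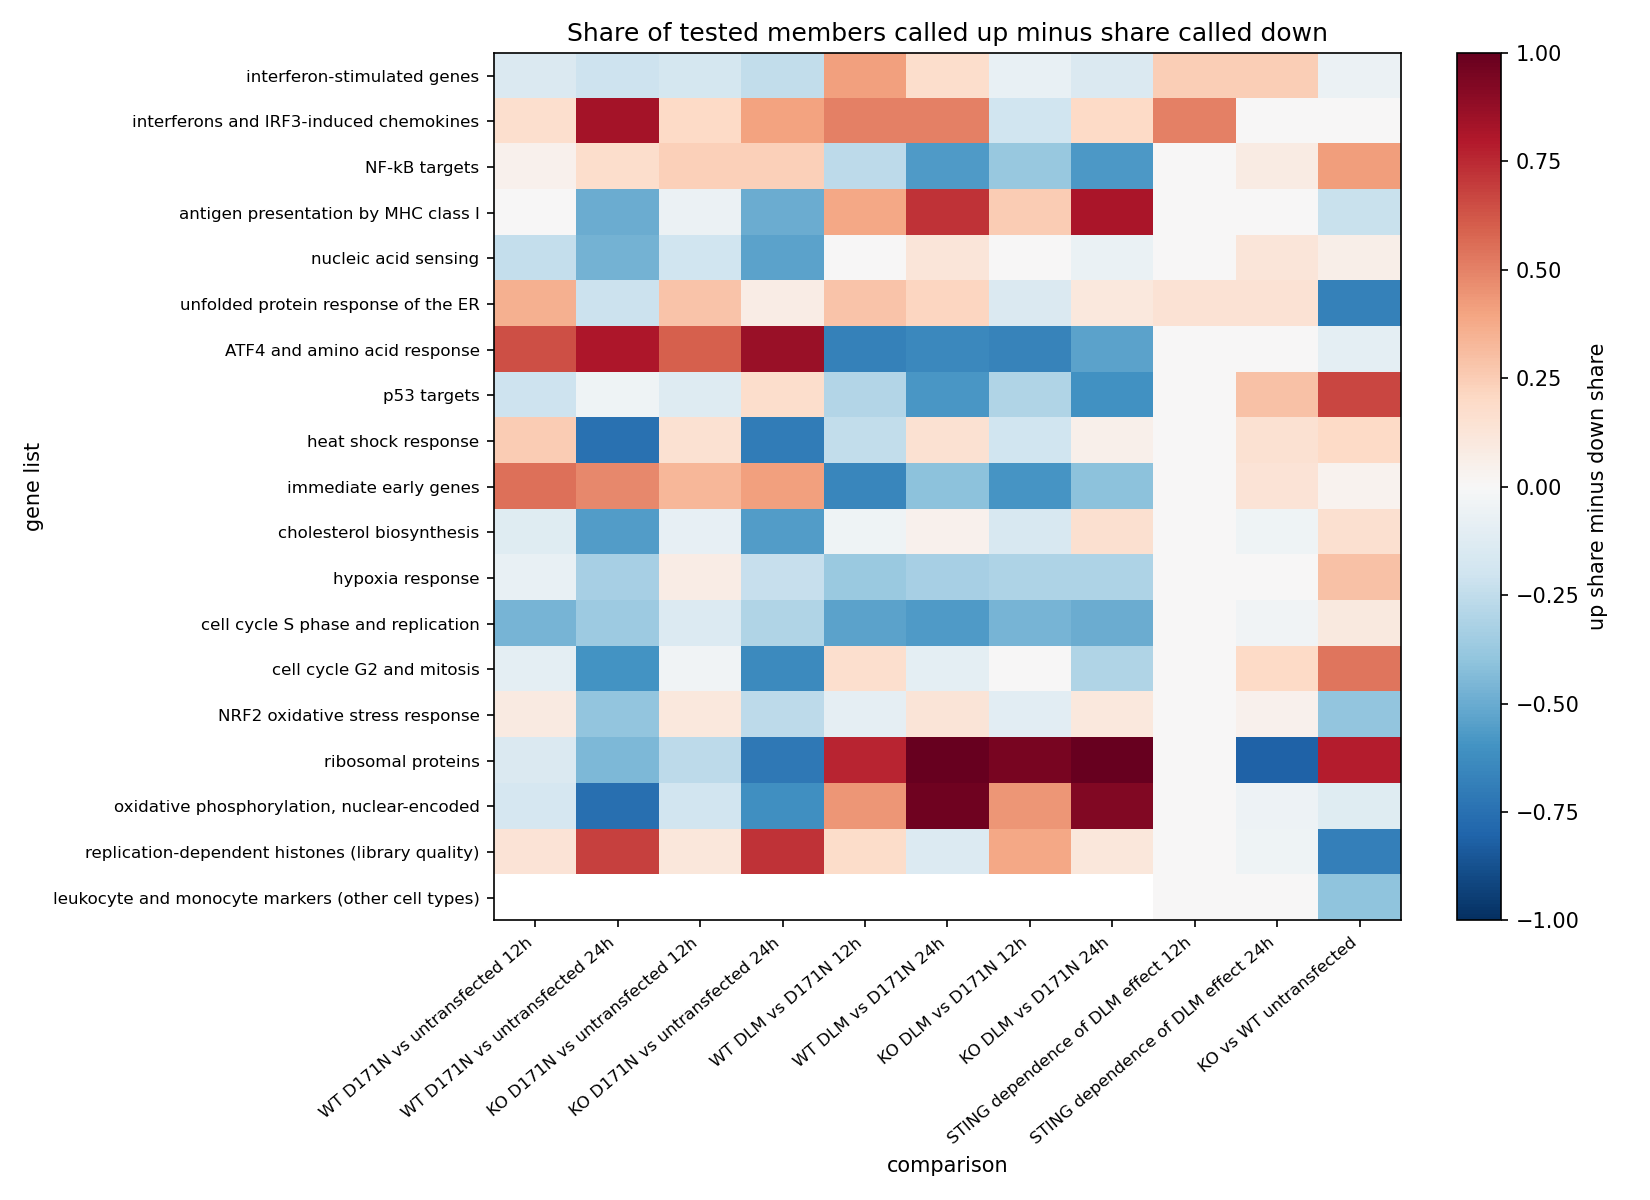
For each gene list and each of the 11 comparisons named below the columns, the share of tested members that edgeR called up minus the share called down at an adjusted p under 0.05. Red marks lists with more rises and blue lists with more falls. Under DESeq2 the balance of the unfolded protein response turned from 11 up and 9 down to 8 up and 10 down for D171N against untransfected knockout cells at 24 h. No other square shown turned with relative log expression size factors or DESeq2.

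The libraries of the 2 lines differed before any transfection. Untransfected knockout cells had almost no mRNA of the patatin-like lipase gene PNPLA4 (−10.54 ± 0.43 against WT, −9.62 with DESeq2) and the prostaglandin reductase PTGR1 (−7.18 ± 0.15, adjusted p = 7.1e-42, 0.238 against 41.9 CPM). Some antiviral and antigen presentation genes were lower as well. Among these were PARP9 (−2.92 ± 0.17), its partner DTX3L (−2.84 ± 0.14), TRIM25, which activates RIG-I (−1.99 ± 0.064), the peptide loader TAPBP (−1.84 ± 0.087) and HLA-B (−0.92 ± 0.061). IFIT1 was higher (0.75 ± 0.11). Of 18 antigen presentation genes 3 were higher and 7 lower (3 and 7 adjusted over the list alone; adjusted p = 0.028, but adjusted p = 0.29 with an estimated correlation). p53 targets were higher in 17 of 24 cases and lower in 1 (17 and 1 adjusted over the list alone; adjusted p = 3.4e-10, and adjusted p = 1.8e-05 with an estimated correlation). The death receptor gene EDA2R was higher by 2.29 ± 0.11. The microRNA-34a host gene MIR34AHG (2.17 ± 0.21), TSPO (2.13 ± 0.17), the stem cell marker LGR5 (1.81 ± 0.063) and DHRS2 (1.81 ± 0.28) were higher. NF-kB targets were higher in 11 of 24 cases and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0061, and adjusted p = 0.034 with an estimated correlation). Replication-dependent histones were lower in 15 of 22 and higher in 0 (16 and 0 adjusted over the list alone; adjusted p = 2.7e-06, and adjusted p = 0.00021 with an estimated correlation). The unfolded protein response was lower in 20 of 28 and higher in 1 (21 and 1 adjusted over the list alone; adjusted p = 2.7e-06, but adjusted p = 0.13 with an estimated correlation). HERPUD1 was lower (−0.78 ± 0.056). NRF2 targets were lower in 13 of 23 cases and higher in 4 (13 and 5 adjusted over the list alone; adjusted p = 0.00033, but adjusted p = 0.13 with an estimated correlation). NQO1 was lower (−1.94 ± 0.18). Of 33 interferon-stimulated genes 7 were higher and 9 lower (8 and 9 adjusted over the list alone; adjusted p = 0.07). edgeR called 7632 of 19901 genes, 3452 higher and 4180 lower in knockout cells, with 115 and 1207 by at least 2-fold. With relative log expression size factors the balance was 4290 and 3628, with DESeq2 3946 and 3097, and with only the compared groups in the fit 4569 and 4527. Line, knockout and any batch in the handling of the libraries go together here, 1 line each. These differences therefore cannot be assigned to STING1, and a batch cannot be told apart from the line.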

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

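The splits of libraries were planned before the data were examined; the tests on IFIT2 and on the size of the 24 h effect were chosen only after the result was seen. Differences of effect between times or lines were examined for how they depend on the grouping of libraries. Between times in WT cells, 9629 genes differed. IFIT1 (−2.98), IFIT3 (−2.39) and HERC5 (−0.52), which belong to the interferon response, had a smaller DLM effect at 24 h, while ALPP (0.26), RPLP0 (0.84) and HLA-C (0.77) had a larger one. MROH2A (3.62), ITGB1BP2 (2.54), PRSS8 (2.47), SOX30 (−2.88), RNF144B (−2.53) and CX3CR1 (−2.48) changed too. In knockout cells 8222 genes differed between times, among them FAM83E (3.18), IFIT2 (2.92), TRIM54 (2.82), ALPP (1.64), RPS18 (1.16), B2M (0.87) and FBXO36 (−2.90). Between lines at 12 h, 30 genes differed, with antiviral genes at the head: IFIT3 (7.11), IFIT1 (6.08), DDX60 (3.44), DDX58 (3.20), ALPP (3.02), IFIT2 (3.02), HERC5 (2.13) and IFI6 (1.23), then PMAIP1 (0.62) and HSPA5 (0.44). At 24 h it was 1210. The WT change minus the knockout change was positive for IFIT3 (4.84), IFIT1 (2.68), DDX58 (1.79), ALPP (1.64), HERC5 (1.43), IFI6 (1.11), ZMAT3 (0.45), CDK1 (0.38) and CCNB1 (0.33). It was negative for CPNE7 (−1.57), LRRN2 (−1.46), H4C5 (−1.01), RPS18 (−0.38) and RPLP0 (−0.38). A positive value need not mean a larger effect in WT cells, since DDX58 fell in knockout cells. Part of the IFIT3 value also came from a fall there.

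Each comparison of 2 groups allows only 10 splits of its 6 libraries, too few for a share under 0.05. In each, the real split was the only 1 of the 10 with that many genes called. Fitted on those libraries alone, DLM against D171N called 5843 genes in WT cells at 12 h and 13308 at 24 h, against at most 1 and 0 in another split, and 3436 and 12865 in knockout cells, against at most 0 and 0. D171N against untransfected gave 6119 and 11510 in WT and 2942 and 9291 in knockout cells, against at most 0 in each. DLM against untransfected gave 8625 (at most 1) and 13684 (0) in WT and 6174 (1) and 12926 (0) in knockout cells. The untransfected lines gave 9096, against at most 0. A mixed split puts the difference between groups into the spread within them, so few calls follow from the mixing itself.

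For differences of differences, 100 splits were drawn for each. The real count was reached in 10 of 100 splits for the change with time in WT cells (real 9431, highest other 11484) and 10 of 100 in knockout cells (7988, 10531). It was reached in 5 of 100 for the difference between lines at 12 h (19, 1489) and 3 of 100 at 24 h (1254, 8582). In each of these comparisons another split of the same libraries reached the real count. Every other split that reached the real count kept or exchanged whole groups on one side, so it still held the DLM effect of one line or time. Among splits without a whole pair of groups, chosen for a look after the result was seen, the highest counts were 0, 0, 1 and 0. There the mixed labels put the DLM effect into the spread within groups, so low counts follow from the mixing. How often the real count was reached depends on how many drawn splits kept a pair whole. The splits therefore cannot decide whether the effects differ between lines or times.

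IFIT2, an interferon-stimulated gene that stood at 5.58 CPM in knockout cells with DLM at 12 h, reached 49.0 CPM there at 24 h, while IFIT1 and IFIT3 did not rise. RNA of WT cells in the knockout libraries is unlikely: PTGR1, PNPLA4 and 1 more gene that only WT cells express stood in the knockout DLM libraries at a median of 0.713% of the WT level (quartiles 0.514% and 2.58%), and 65.2% would be needed. Of 11 other interferon-stimulated genes raised in WT cells at 12 h and tested in knockout cells, 3 rose there at 24 h and 2 fell. Those that rose were DHX58 by 3.66, IFI27 by 0.58, and IFI6 with edgeR adjusted p = 8.1e-07. The median change of the 11 was 0.19, against 0.98 in WT cells at 12 h, where they were picked for having risen. Over all genes of that knockout comparison, 5957 of 16879 rose and 6480 fell. So the WT pattern of 12 h was not repeated in knockout cells at 24 h. The WT effect on IFIT1 and IFIT3 had itself shrunk by 24 h, so this cannot exclude weak or late STING signalling in the knockout line. Outside the 11, ISG15 (1.01) and ALPP (1.85) rose in knockout cells at 24 h and DDX58, picked after the values were seen, fell by 1.86. Part of STING signalling or a route without STING may remain, and no test here bears on either.

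The 1210 genes whose 24 h effect differed between lines were mostly genes beyond the interferon response, such as RPS18 and CDK1. Of those tested in all fits, 90.3% (1074 of 1189) differed against the direction in which both lines changed together. This means that their WT change was smaller in size than the knockout change, so it describes the difference and tests no cause. Whether fewer counts in the knockout libraries contributed could not be decided. The slope of WT on knockout changes was 0.845 among 4941 abundant genes, and 0.792 to 0.886 over 9 combinations of single libraries. Noisier knockout changes would also lower this slope, and that part was not separated. IFIT1, IFIT3 and HERC5 lie off the line of that slope. Whether the share of transfected cells differed between lines could not be tested, since plasmid reads are not in the tables.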

How the results depend on the processing

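No call of a named gene turned to the opposite direction under any alternative, and no list test did with an estimated correlation or the replicate block. Genes whose fold moved by over 1.5 times without 1 library, with DESeq2 or with the replicate block had mostly been left unnamed. The stability of the named genes, and how few of them lost calls, was therefore partly fixed by that choice. The balance of up and down calls turned, with relative log expression size factors and DESeq2, for D171N against untransfected at 24 h (WT 5683 up and 6052 down, and 4744 and 5547; knockout 4248 and 4711, and 3537 and 4238) and between untransfected lines (4290 and 3628, and 3946 and 3097). It turned with only the compared groups for D171N against untransfected at 12 h (WT 3068 up and 3051 down, knockout 1483 and 1459, and 1402 and 1326 without knockout D171N replicate a), for DLM against untransfected knockout cells at 12 h (3126 and 3048) and between untransfected lines (4569 and 4527), and with all 30 libraries for WT D171N at 24 h (5475 and 5738). The fold threshold turned it at 12 h to mostly up in each comparison of 2 groups, and for the difference between lines at 24 h to 21 up and 62 down. Asking for a fold of at least 2 left fewer genes in each comparison. For DLM against D171N it left 486 and 3703 in WT cells at 12 h and 24 h and 613 and 4104 in knockout cells. For D171N against untransfected it left 273, 2026, 182 and 1361, and for DLM against untransfected 982, 4896, 1088 and 4619, in the same order. It left 1514 for the change with time in WT and 1631 in knockout cells, 9 and 83 for the differences between lines at 12 h and 24 h, and 1322 between untransfected lines; this follows from the threshold. The difference between lines at 12 h called 19 genes with only the compared groups in the fit, and that at 24 h 742 with no filter on low counts (321 up, 421 down); the cause was not tested. Leaving out 1 library gave 17 to 80 genes for the difference between lines at 12 h (17 without knockout D171N replicate c, 80 without a), 764 to 1163 at 24 h (764 without WT DLM replicate b), and 2091 to 4041 for D171N against untransfected knockout cells at 12 h (2091 without untransfected replicate b); the cause was not tested. All other totals stayed within 1.5 times, in 121 of 126 cases for single libraries, but some counts in 1 direction moved further. With DESeq2 those up in WT cells at 12 h were 1619 for DLM against D171N and 2281 for DLM against untransfected, and without knockout DLM replicate b those up in knockout cells at 12 h were 1350. Those down in the difference between lines ran from 0 to 21 at 12 h without 1 library, and at 24 h were 265 with only the compared groups and 255 without knockout DLM replicate a. Of the named gene values, 73 fell under the fold threshold. Beyond that only STING1 in knockout cells lost calls, 2 with DESeq2, 2 with no filter, 1 with only the compared groups, 1 with relative log expression size factors and 7 without 1 library. Of the 309 list tests, 113 lost their call with an estimated correlation and 196 did not change. The 196 include tests that passed under neither setting, so the share of called tests that lost their call was higher than 113 of 309. Replicate letters did not pair the libraries: deviations of libraries with the same letter correlated at a mean of 0.00262 in WT and −0.039 in knockout cells over 30 pairs each, and 6 and 3 of 15 libraries were closest to their own letter. With the replicate block the differences between lines called 24 genes at 12 h and 1104 at 24 h, no count moved by over 1.5 times, and of the list tests 2 were lost (heat shock for DLM against D171N in WT cells at 12 h, adjusted p = 0.051, and S phase for D171N against untransfected knockout cells at 24 h, adjusted p = 0.057) and 1 gained. Knockout libraries, with a median of 12.3 M counts against 20.6 M, allowed 16879 genes to be tested against 19368 in WT cells. A 1.5-fold change was recovered for 66% of simulated genes in the difference between lines at 12 h, so part of the changes of that size would be missed. The simulated data held no broad shift between groups, so recovery in the real comparisons may differ from this.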

Other observations

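The gene families, the length of genes and the tests below were chosen only after the result was seen. Zinc finger genes named ZNF, most of which encode repressors of transcription, moved as a block. Of 394 tested in WT cells, 282 were higher and 22 lower with D171N than without transfection at 24 h (median 0.45; adjusted p = 0.00042 with an estimated correlation), and 35 were higher and 305 lower with DLM than with D171N (median −0.73; adjusted p = 0.00039 with an estimated correlation). In knockout cells, of 384 tested, these were 271 and 18 (median 0.43; adjusted p = 0.0097 with an estimated correlation) and 38 and 297 (median −0.70; adjusted p = 0.035 with an estimated correlation). The 2 comparisons share the D171N libraries, so their opposite signs are not independent. Against untransfected cells DLM left 100 higher and 172 lower in WT cells (adjusted p = 0.18) and 88 and 174 in knockout cells (adjusted p = 0.073), and neither passed. Host genes of small nucleolar RNAs named SNHG, whose spliced RNAs are removed by decay coupled to translation, were higher with DLM than without transfection at 24 h in 21 of 24 cases in WT cells (median 1.14; adjusted p = 0.0071 with an estimated correlation) and 21 of 23 in knockout cells (median 1.37; adjusted p = 0.014 with an estimated correlation). D171N alone raised 18 and lowered 1 in WT cells (median 0.61; adjusted p = 0.0062 with an estimated correlation) and 15 and 1 in knockout cells (median 0.42; adjusted p = 0.014 with an estimated correlation). DLM against D171N gave 15 up and 6 down in WT (median 0.26; adjusted p = 0.012, but adjusted p = 0.19 with an estimated correlation) and 17 and 4 in knockout cells (median 0.70; adjusted p = 0.041 with an estimated correlation). In the difference between lines at 24 h, 0 of them were called higher by edgeR and 15 lower (0 and 12 with DESeq2; median −0.37; adjusted p = 0.00039 with an estimated correlation). HOX genes, the segment identity factors, rose with DLM against D171N at 24 h in 22 of 36 cases and fell in 6 in WT cells (adjusted p = 7.7e-07, but adjusted p = 0.055 with an estimated correlation), and 20 and 6 in knockout cells (adjusted p = 0.00087, but adjusted p = 0.067 with an estimated correlation). D171N had lowered them against untransfected cells, with 2 up and 28 down in WT (adjusted p = 5.7e-06, but adjusted p = 0.068 with an estimated correlation) and 2 and 23 in knockout cells (adjusted p = 0.047 with an estimated correlation). DLM against untransfected cells gave 15 up and 10 down in WT (adjusted p = 0.071) and 17 and 13 in knockout cells (adjusted p = 0.17). These directions were the same with relative log expression size factors and with DESeq2.

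Long genes fell with DLM against D171N at 24 h in both lines, while genes under 3 kb were closer to even (126 up and 96 down of 256 in WT, 123 and 98 in knockout cells). Across protein-coding genes of at least 5 CPM (10496 in WT cells, 10494 in knockout cells), the Spearman correlation of genomic span with the log2 change was −0.28 in WT and −0.29 in knockout cells, and −0.21 and −0.19 at 12 h. Median changes ran from 0.12 and 0.15 for genes under 3 kb to −0.43 and −0.49 for genes over 100 kb, of which 1565 of 2277 fell in WT cells and 348 rose. Exon length correlated less (−0.16 and −0.17), and for D171N against untransfected cells at 24 h the correlation with span was −0.06 in WT and 0.05 in knockout cells.

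Genes rarely detected in untransfected cells gained counts at 24 h with DLM against D171N where they lay close to expressed genes. Summed over 596 such genes with expressed genes on both sides, counts rose 2.15 times in WT cells (1.88 to 2.42 between single libraries) and 3.06 times in knockout cells (2.35 to 4.03). The gain was not particular to DLM. D171N at 24 h had already raised this sum over untransfected cells, from 27.2 to 60.1 CPM in WT and from 21.1 to 49.5 CPM in knockout cells. Far from expressed genes the sums also rose with D171N, from 304 to 553 and from 235 to 425 CPM. All these genes were picked for low levels in untransfected cells. Genomic DNA in the libraries is unlikely as the main cause of the gain with DLM over D171N between expressed genes. The 22314 rarely detected genes far from expressed genes had ratios of 0.924 in WT (0.751 to 1.09) and 1.21 in knockout cells (1.01 to 1.46). For the rise with D171N over untransfected cells, which the far genes shared, genomic DNA was not tested. Rarely detected genes overlapping expressed genes had DLM to D171N ratios of 1.35 in WT and 1.69 in knockout cells. Transcription past the ends of expressed genes could not be told apart from other sources. Downstream of expressed genes the ratio was 1.41 in WT and 1.96 in knockout cells, against 1.31 and 1.80 upstream, and the ranges over single libraries overlapped.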
